A study of Macaca mulatta with 34 samples.

How the data were processed

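Total RNA was measured in deep cerebellar nuclei (DCN) of rhesus macaques after injection of adeno-associated virus (AAV) vectors that carry RNA interference cargo, and small RNA was measured in cerebellar tissue from the same 2 studies. Per the labels' protocols, DCN RNA was extracted with TRIzol and RNeasy, depleted of ribosomal RNA with human/mouse/rat FastSelect and made into directional NEBNext Ultra II libraries. Small RNA was extracted with miRNeasy and made into TruSeq Small RNA libraries, per the same protocols. The genome build and the annotation release are not given in the sources used here, and no genome sequence was at hand, so no read was realigned and no genomic position was used.

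The deposited files hold read counts per gene that the authors made. Per the submitters' processing notes, reads were aligned with STAR 2.6.0c and the authors compared groups with DESeq2, whose version is not given in the sources used here. All 10 DCN libraries of Study 1, 2 intmiS1 libraries of Study 2 and the small RNA libraries of Study 2 came as STAR gene-count tables with 1 unstranded and 2 stranded columns. The other 10 DCN libraries of Study 2 came as featureCounts tables of counts made from STAR alignments. Per the file headers, featureCounts was run so that a read overlapping several genes counted in each of them. The tables of Study 1 small RNA hold counts per gene as deposited by the authors, and the program that made them is not given in the sources used here. The reverse column was used for Study 1 DCN libraries and the sense column for Study 2 small RNA. The unstranded column was used for the 2 intmiS1 libraries, because the featureCounts tables followed it more closely (mean Spearman correlation 0.917) than the reverse column (0.889). The tables together hold 34847 gene identifiers, of which 24009 have a symbol and 540 are microRNA genes. Each fit used the identifiers present in all of its libraries. Vector features were counted separately and left out of the gene tests.

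Assigned counts in Study 1 DCN libraries ranged from 2049685 to 4810852, apart from 1 vehicle library with 87741. In Study 2 the featureCounts libraries held 20978241 to 39792653, and the 2 STAR intmiS1 libraries 5169866 and 4858179. Study 1 small RNA libraries held 4756968 to 10629988. Study 2 small RNA libraries held 347 to 2795, apart from 1 empty capsid library with 277509, and 99.946% to 99.989% of the reads in the others were unmapped. The share of reads naming no gene was 62.1% to 71.1% in Study 1 DCN, and 68.4% and 71.2% in the 2 STAR intmiS1 libraries. Intervals on single-library shares are exact Poisson 95% intervals, a count of 0 has an upper limit of 3 counts, and both cover counting error only. Replicates are separate animals per the labels' identifiers where these are given. The labels give none for Study 1 small RNA. The p values of edgeR, DESeq2 and the permutation tests measure spread between these samples. Camera sets the genes of a list against the other genes, so with the preset correlation its p does not measure that spread.

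Groups, comparisons, gene lists, named genes and a first set of alternatives were written down before the data were examined. Tests used R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test), limma 3.58.1 (camera) and DESeq2 1.42.0. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and p values were adjusted by Benjamini-Hochberg within a comparison at 0.05. Fold changes used a prior count of 0.125, log expression used a prior count of 2, and standard errors (SE) of log2 fold changes were approximated from the F statistic. Gene values in the text are CPM after TMM, as mean ± SD, and vector and small RNA values are RPM over the counts in genes without TMM. TMM could not be computed for Study 2 small RNA, which was scaled by total counts alone. The 9 featureCounts libraries of the empty capsid, StufferOnly and miSCA7Stuffer groups were fitted together, all 12 DCN libraries of Study 2 for intmiS1, and all 22 DCN libraries for the difference between studies. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.

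Each gene list (44 in all, 40 of them for DCN) was tested with camera when at least 5 members were tested, using the preset correlation between genes of 0.01. The adjusted p with a correlation estimated from the samples is given beside it. A count adjusted over the list alone corrects only over that list's members. Some genes belong to more than 1 list, among them CD44, ITGAX, CXCL10, CCL5, COL1A1, COL1A2 and CSPG4. Exact permutation tests of the group labels were two-sided. Named genes are ATXN1 and ATXN7 in every library, the 8 rises and 8 falls with the largest log2 fold change among called genes with a symbol and a mean of at least 1 log2 CPM, and up to 3 members with the smallest p of each list that passed or was named in advance. Where no gene passed, the 4 smallest p on each side were taken as values. In small RNA the rule took up to 10 microRNA genes, or the 4 with the smallest p, and 5 microRNAs named in advance. Other genes were chosen after the values were seen.

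The alternatives were RLE scaling in edgeR, no expression filter, DESeq2, leaving out each library in turn, blocking on replicate number (genes alone), fitting only the 6 libraries compared, the unstranded or other STAR column, the format of the animal identifier as a covariate, only featureCounts libraries, leaving out the 2 intmiS1 libraries of the other file type, microRNA genes alone, and the estimated correlation. Others were added after the data were seen and are named in the closing section. The median log2 fold change over all genes moved by more than 0.1 with DESeq2 in Study 1 DCN (-0.156 against 0.018) and in the difference of effects (-0.338 against 0.036), and with total counts alone in Study 1 small RNA (0.914 against 0.061). It also moved with the replicate block in Study 1 small RNA (-0.08 against 0.061) and without empty capsid replicate 2 in StufferOnly against empty capsid (-0.08 against 0.021). In Study 2 small RNA (0.804) it was -2.349 without a filter, 2.009 with the block and 0.211 to 1.465 without single libraries.

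Replicate numbers were checked for pairing. Residuals of equally numbered libraries correlated at 0.18 to 0.45 between miSCA7Stuffer and StufferOnly, where 5 of 6 libraries were closest to the library of their own number, and blocking on the number there gave 0 called genes. No 2 of the 45 pairs of libraries checked for duplication were identical.

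The tests were tested on simulated data, drawn from negative binomial distributions with the fitted spreads and the same mean for a gene in every group. In these data 100 genes were changed 8-fold and 100 genes 2-fold, all taken from genes with a mean above 5 CPM. In Study 1 DCN (13101 genes) 82% of the 8-fold and 17% of the 2-fold genes were recovered with 3 unchanged genes called. In StufferOnly against empty capsid (20272 genes) it was 90% and 14% with 5. In intmiS1 against empty capsid (20959 genes) it was 86% and 20% with 6. In the difference of effects (16021 genes) it was 78% and 9% with 3. In Study 1 small RNA (7665 genes) it was 14% and 0% with 0. DESeq2 recovered 96% and 31% in Study 1 DCN (13101 genes) with 32 unchanged genes called, and 99% and 47% in StufferOnly against empty capsid (20272 genes) with 68. Camera called a raised list in each of these with either correlation. The simulated genes vary independently of each other, so this does not test how often camera calls unchanged lists of correlated genes. Real libraries can depart from this model, and weakly expressed genes were not changed in it. A count of 0 called genes therefore does not show that 8-fold changes are absent.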

Results

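Total RNA was sequenced from deep cerebellar nuclei (DCN), the output nuclei of the cerebellum, of rhesus macaques injected there under magnetic resonance guidance. In Study 1, 6 libraries came from animals given AAV.miS1, a vector that expresses an artificial microRNA against ATXN1, and 4 from animals given vehicle. In Study 2, 3 libraries came from each of 4 groups: empty capsid, intmiS1, miSCA7Stuffer and StufferOnly. By their labels, intmiS1 is a construct of the ATXN1 microRNA, miSCA7 is aimed at ATXN7, and the stuffer is filler sequence. Small RNA was sequenced from 3 AAV.miS1 and 3 vehicle libraries in Study 1, and from 3 intmiS1 and 3 empty capsid libraries in Study 2. Study 1 asked what caused the toxicity of AAV.miS1, and Study 2 characterised the responses to redesigned constructs.

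Depth differed widely between the sets. In Study 1 the 4 vehicle libraries held 2270423, 87741, 3439609 and 2976749 counts in genes, and the 6 AAV.miS1 libraries 4810852, 3747235, 2804278, 4125398, 2948222 and 2049685. In Study 2 the empty capsid libraries held 39792653, 28496977 and 31443741, the intmiS1 libraries 5169866, 4858179 and 32289107, the miSCA7Stuffer libraries 33001265, 26505043 and 20978241, and the StufferOnly libraries 32618716, 22183232 and 32088197. The Study 1 small RNA libraries held 4756968, 9879519 and 4931347 counts with AAV.miS1 and 7421542, 10629988 and 8409548 with vehicle. Those of Study 2 held 1626, 2795 and 2238 with intmiS1 and 451, 277509 and 347 with empty capsid.

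Vector sequence was present in the tissue of every vector group, at levels that differed many-fold between animals. In Study 1, AAV.miS1 libraries held 138.5 ± 204 vector RPM (reads per total reads in genes, scaled as CPM; SD, n = 6, 22.2 to 548) and vehicle libraries 4.79 ± 5.21 (n = 4, 0.337 to 11.3). All 6 AAV.miS1 libraries lay above all 4 vehicle libraries (two-sided exact permutation p = 0.21 on the raw scale and 0.00476 on the log scale, the smallest the design allows). The highest vehicle value, 11.3 RPM in replicate 2, is 1 read (exact Poisson 95% interval 0.286 to 62.9), which covers the 22.2, 24 and 28.9 RPM of AAV.miS1 replicates 1, 5 and 6. Vehicle replicate 3 held 23 vector reads, or 6.71 RPM (exact Poisson 95% interval 4.26 to 10.1), above its floor of 0.876 RPM. Vector reads in that control library are thus more than counting error, and their source was not tested. StufferOnly libraries held 407.5 ± 195 (n = 3) and miSCA7Stuffer libraries 202.7 ± 180 (n = 3), against 0.207 ± 0.0666 (n = 3) with empty capsid (two-sided exact permutation p = 0.1 for each, the smallest 3 against 3 allows). Within miSCA7Stuffer, replicate 1 held 1.64 RPM and the other libraries 349 and 257. Replicates 1 and 2 of intmiS1 held 568 and 648 RPM on 1 reference sequence of their construct, and replicate 3 held 44.6 on another, so these values cannot be compared. Reads in the RNAi expression cassette were 5.49, 7.17 and 3.24 RPM in StufferOnly libraries, 0, 11.4 and 7.63 in miSCA7Stuffer libraries and at most 0.0251 with empty capsid. Reads in the primary microRNA sequence were 4.63, 5.54 and 2.49 RPM in StufferOnly libraries and 0, 5.32 and 3.96 in miSCA7Stuffer libraries. In these featureCounts tables a read that overlaps several vector features counts in each of them. In the STAR counts of Study 1, the stuffer, cassette and primary microRNA features were at 0 in every DCN library. The vector RPM of Study 1 were thus counted otherwise and cannot be set against those of Study 2.

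In the DCN of animals given AAV.miS1, genes of innate and adaptive immunity rose against vehicle. CHI3L1, a secreted protein of reactive astrocytes, was 624.5 ± 142 CPM (SD, n = 6) against 94.1 ± 28.7 (n = 4; log2 fold change 2.77, SE 0.27, adjusted p = 0.00561, higher in 6 of 6 AAV.miS1 libraries than in any vehicle library). OASL and BST2, both induced by interferon, rose by 5.17 (17.35 ± 9.95 against 0.332 ± 0.241 CPM) and 3.65 (22.7 ± 10.3 against 1.38 ± 0.947). SERPING1 and CFB, both of the complement system, rose by 2.88 and 3.60, and the monocyte attractants CCL2 and CCL3 by 3.42 and 4.60. CD68 and MSR1 of macrophages rose by 5.79 (770.1 ± 693.6 against 21.7 ± 20.5 CPM) and 5.48, and TREM2, a receptor of activated microglia, by 3.86. B2M of MHC class I rose by 3.62, and CD74, the chaperone of MHC class II, by 3.69 (4133 ± 3584 against 333.7 ± 214.8 CPM, with overlap between the groups). Lymphocyte genes rose as well, among them NKG7 and GZMK of cytotoxic cells (6.28 and 5.53) and THEMIS of T cells (5.26). LCK, the T cell kinase, and TNFSF14, a lymphocyte cytokine, were at 0 in all 4 vehicle libraries, and their means of 8.98 and 4.98 CPM were at least 26.9-fold and at least 14.9-fold higher than a floor of 3 counts over the vehicle group. The adjusted p of these genes, from edgeR, ranged up to 0.0394, and all but CD74 were higher in 6 of 6 AAV.miS1 libraries than in any vehicle library.

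The lists fixed in advance moved the same way. Of 39 interferon-stimulated genes tested, 24 rose (35 adjusted over the list alone, median log2 fold change 2.45, camera adjusted p = 3.55e-14). All 9 MHC class II genes rose (9 adjusted over the list alone, median 4.23), as did 14 of 16 complement genes (16, 2.96), 14 of 21 genes of activated microglia and macrophages (18, 3.41) and 9 of 11 of MHC class I (10, 2.04). Of T cell genes 7 of 13 rose (12, 4.48, also with its 2 members absent from vehicle at their bound), of cytotoxic lymphocytes 7 of 8 (7, 4.93) and of B and plasma cells 3 of 8 (6, 3.39). Chemokines and cytokines (11 of 16; 15), NF-kB response (8 of 14; 12), nucleic acid sensing (6 of 17; 14), microglia (7 of 12; 9) and reactive astrocytes (9 of 16; 11) also passed upward. Other lists also passed upward by camera: extracellular matrix (13 of 23; 18), p53 response (8 of 19; 14), apoptosis and pyroptosis (8 of 21; 16), immediate early genes (8 of 13; 9), proliferation (7 of 15; 12) and the unfolded protein response (2 of 19, ATF3 and PPP1R15A; 10). CDKN1A, the p53 target that stops the cell cycle, was 152.8 ± 172.5 CPM against 3.04 ± 3.01 (5.23, adjusted p = 0.0275, higher in 6 of 6). Camera passed 29 lists with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.22.

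Genes of neurons and of oligodendrocytes lay lower with AAV.miS1, although few passed singly. The Purkinje cell genes CALB1, a calcium buffer, and SLC1A6, a glutamate transporter, fell by 2.11 (10.5 ± 6.68 against 43.0 ± 25.9 CPM, adjusted p = 0.0467) and 2.38 (0.0399) on the log2 scale. CALB1 was lower in 6 of 6 AAV.miS1 libraries than in any vehicle library, while SLC1A6 overlapped between the groups. CAMK2B, a synaptic kinase, fell by 1.00 (73.04 ± 22.9 against 144.8 ± 15.8 CPM, adjusted p = 0.0358, lower in 6 of 6). SREBF2, HMGCS1 and SQLE of cholesterol synthesis fell by 0.87, 1.09 and 1.39, each lower in 6 of 6. As lists, 3 of 22 Purkinje genes fell (4 adjusted over the list alone, median -1.17, camera adjusted p = 1.62e-06) and 0 of 18 granule cell genes by edgeR, although all 18 lay below 0 (0, -1.37, 2.88e-07). General neuronal genes (1 of 28; 1, -0.99), DCN projection neurons (0 of 15; 0, -0.84), inhibitory interneurons (0 of 14; 0, -0.83), astrocytes (0 of 15; 0, -0.72) and oligodendrocyte precursors (0 of 10; 0, -0.60) passed downward by camera. So did oligodendrocytes and myelin (0 of 16; 6, median -0.595), cholesterol synthesis (3 of 20; 3, median -0.575) and the mitochondrial respiratory chain (0 of 28; 0, -0.38). With an estimated correlation the adjusted p of these lists ranged from 0.22 to 0.379.

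Other lists did not pass in Study 1. Genes of microRNA biogenesis had a median of 0.01 and a mean of 0.13 with the test pointing down (adjusted p = 0.796, and 0.882 with an estimated correlation), and TUT7, which adds uridine to microRNA precursors, was the 1 of 17 that rose (1 adjusted over the list alone). TUT7 was 168.4 ± 80.8 CPM against 50.9 ± 27.6 (1.55, adjusted p = 0.0436, higher in 6 of 6). Heat shock genes had 0 of 13 past the threshold, with a median of 0.04, a mean of -0.06 and a test pointing down (0.551). Oxidative stress genes had 1 of 15 (5 adjusted over the list alone, 0.917), meninges 2 of 10 (5 up and 1 down, 0.319), histones 0 of 9 (0.0644) and the ATXN1 complex 0 of 10 (1 up and 2 down, median 0.03 with the test pointing down, 0.699). Endothelium (0 of 14, median -0.13 and mean 0.08, test down) and pericytes (0 of 11, median -0.26 and mean 0.02, test down) both had an adjusted p of 0.796. Choroid plexus had 2 members tested and red blood cells 0.

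ATXN1, the target of the microRNA, was 62.1 ± 14.6 CPM with AAV.miS1 (SD, n = 6, 49.6 to 90.2) and 96.6 ± 5.86 with vehicle (n = 4, 91.2 to 104), or 64.3% of the vehicle mean. It was below every vehicle library in 6 of 6 AAV.miS1 libraries (two-sided exact permutation p = 0.0143, smallest possible 0.00476). Across all genes the edgeR test did not pass (log2 fold change -0.62, SE 0.18, adjusted p = 0.0604). It passed when adjusted over the list of vector target genes alone. That list holds only 2 members, ATXN1 and ATXN7, so it corrects for little. Without AAV.miS1 replicate 1, the library with the highest ATXN1, the change was -0.75 with an adjusted p of 0.0208, and over all alternatives the adjusted p ranged from 0.0208 to 0.405. The vehicle value of 104 rests on 10 counts. Neuron lists lay lower in the same libraries, with medians of -0.99 for general neuronal genes and -1.17 for Purkinje cells. In bulk tissue a fall of ATXN1 within cells cannot be told apart from a change in the cells sampled. ATXN7, the target of the other construct, did not pass (76.6 ± 12.3 against 62.7 ± 15.9 CPM, 0.21, adjusted p = 0.455).

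**Figure D1:**
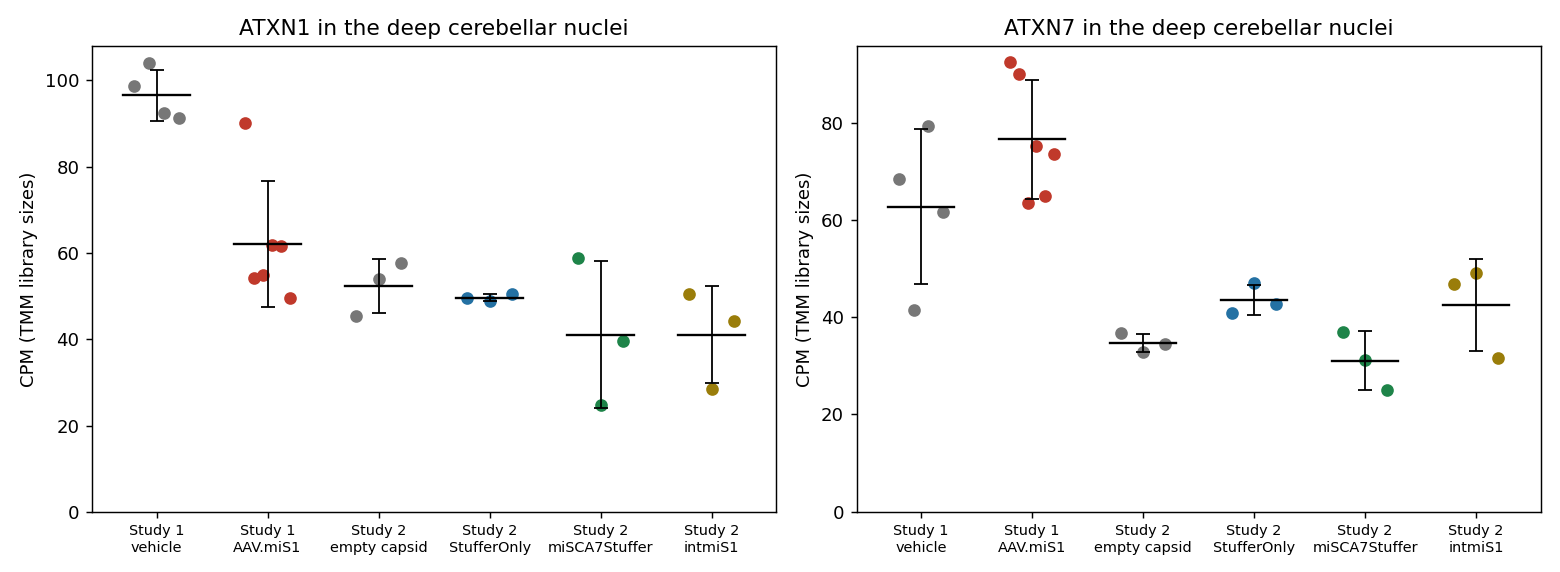
ATXN1 and ATXN7 CPM in each DCN group, with points for libraries, a line for the mean and bars for the SD. ATXN1 with AAV.miS1 (49.6 to 90.2) lies below all vehicle libraries (91.2 to 104).

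By edgeR, 1004 of 13383 genes passed in Study 1, 966 up and 38 down (3592 at an unadjusted p under 0.05, and 1816 by DESeq2). Of the 1004 called genes, 677 did not overlap between the groups. Of all genes tested, 1000 were higher in every AAV.miS1 library than in every vehicle library and 386 lower, where chance gives 64 each way, or 0.952% both ways. The count rested on single libraries. It was 1, 2, 0 and 2 without vehicle replicates 1 to 4 (for the 0, edgeR had 2583 at an unadjusted p under 0.05), and 941, 505, 556, 3, 2300 and 1315 without AAV.miS1 replicates 1 to 6. The share of unmapped reads split the libraries into a set over 15% (vehicle replicates 2 to 4, AAV.miS1 replicates 5 and 6) and a set under 15%. Within the first set 123 genes passed, 116 of them among the 1004, and with the set as a covariate 148 passed. In the second set, which had 1 vehicle library, edgeR called 0 with 2458 at an unadjusted p under 0.05, and DESeq2 was not run on it.

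In animals given StufferOnly, which by its label carries filler alone, DCN genes of inflammation rose and genes of myelin fell against empty capsid. GPNMB, a glycoprotein of lipid-laden macrophages, was 4579 ± 1284 CPM (SD, n = 3) against 5.38 ± 2.18 (n = 3; 9.73, SE 1.91, adjusted p = 0.0201, higher in 3 of 3). CHIT1, a macrophage chitinase, and IGHM, the heavy chain of IgM, rose by 10.98 and 10.05. APOE, a lipid carrier, was 2540 ± 220 against 400.8 ± 13.6 CPM (2.66), C1QB of complement 337.6 ± 29.5 against 17.1 ± 4.89 (4.30), and CD74 2398 ± 903 against 239.2 ± 46.3. Interferon-induced BST2 rose by 2.92 (adjusted p = 0.0109, 25.5 ± 9.49 against 3.35 ± 0.566 CPM, higher in 3 of 3). CCL18, a lymphocyte attractant, was at 0 in all 3 empty capsid libraries, and its 22.5 ± 6.11 CPM was at least 717-fold higher than a floor of 3 counts over that group. Of the myelin genes, MOBP fell by 1.27 (676.2 ± 45.1 against 1626 ± 263 CPM, adjusted p = 0.0164, lower in 3 of 3), and BCAS1, made by young oligodendrocytes, stood at 247.9 ± 16.7 against 595.6 ± 10.8. None of these genes overlapped between the groups.

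As lists, all 9 MHC class II genes rose with StufferOnly (9 adjusted over the list alone, median 3.38), as did 14 of 16 complement genes (14, 2.69), 15 of 24 T cell genes (24, 4.81) and 16 of 39 interferon-stimulated genes (29 with 2 down, 1.63, camera adjusted p = 6.51e-07). Activated microglia and macrophages had 16 of 21 up and LPL down (18 and 1, 3.56), cytotoxic lymphocytes 9 of 13 (12, 4.04), B and plasma cells 11 of 17 (15 with 1 down, 4.60) and microglia 6 of 12 (7 with 2 down, 1.16). The medians of T cells, cytotoxic lymphocytes and B and plasma cells were the same with the member absent from empty capsid at its bound. Nucleic acid sensing (12 of 18; 15), MHC class I (7 of 11; 11), chemokines (12 of 22; 15), NF-kB response (9 of 14; 12), reactive astrocytes (12 of 18; 12), apoptosis (16 of 22; 17), p53 response (7 of 21; 13), immediate early genes (11 of 16; 13), proliferation (4 of 22; 11) and extracellular matrix (11 of 24; 14) passed upward. The unfolded protein response had 10 of 21 up and DNAJB9 down (15 and 1, 0.69). Camera passed 28 lists with the preset correlation and 0 with an estimated correlation (lowest adjusted p 0.377).

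Downward with StufferOnly went oligodendrocytes and myelin (9 of 16; 12 adjusted over the list alone, median -0.79, camera adjusted p = 5.6e-07), their precursors (3 of 10; 5, -0.64) and astrocytes (1 of 15; 7, -0.97). Some neuron lists, though not granule cells, passed downward by camera with few or no single calls: Purkinje cells (1 of 24, DNER; 1, -0.66), DCN projection neurons (1 of 19, MEIS1; 1, -0.81), inhibitory interneurons (0 of 15; 0, -0.61) and general neuronal genes (0 of 29; 0, -0.79). DNER, a Notch ligand of Purkinje cells, was 289.3 ± 14.3 against 487 ± 48 CPM (-0.75, adjusted p = 0.0181, lower in 3 of 3). Cholesterol synthesis had 7 of 20 down (11) and FDFT1, which makes squalene, up at 2862 ± 1295 against 276.6 ± 13.7 CPM (3.37, adjusted p = 0.02, higher in 3 of 3). The respiratory chain had 2 of 28 down (2, -0.50). With an estimated correlation these lists had adjusted p of 0.377 to 0.543. Granule cells had 0 of 18 with a median of -0.07, a mean of 0.46 and a test pointing down (0.54, and 0.867 with an estimated correlation).

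The remaining lists did not pass with StufferOnly. MicroRNA biogenesis had DGCR8, of the microprocessor, and TUT7 up (0.55 and 1.36; 2 of 19, 0 adjusted over the list alone, adjusted p = 0.502). Oxidative stress had 5 of 16 up and 2 down (6 and 6 adjusted over the list alone, median -0.40, mean 0.09, 0.54). Heat shock had 1 of 13 down (0.125), endothelium 2 of 14 up with a median of -0.47 (0.261), pericytes 1 up and 2 down of 12 (0.297) and the ATXN1 complex 2 up and 1 down of 11 (0.723). Meninges had 2 of 11 up (6, 0.0692), histones 0 of 9 (0.272) and choroid plexus 0 of 9 (0.837), and red blood cells had 2 members tested. ATXN1 (49.3 ± 0.876 against 52.1 ± 6.18 CPM, -0.08, adjusted p = 0.862) and ATXN7 (43.3 ± 3.2 against 34.5 ± 1.89, 0.33, 0.182) did not pass.

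**Figure D2:**
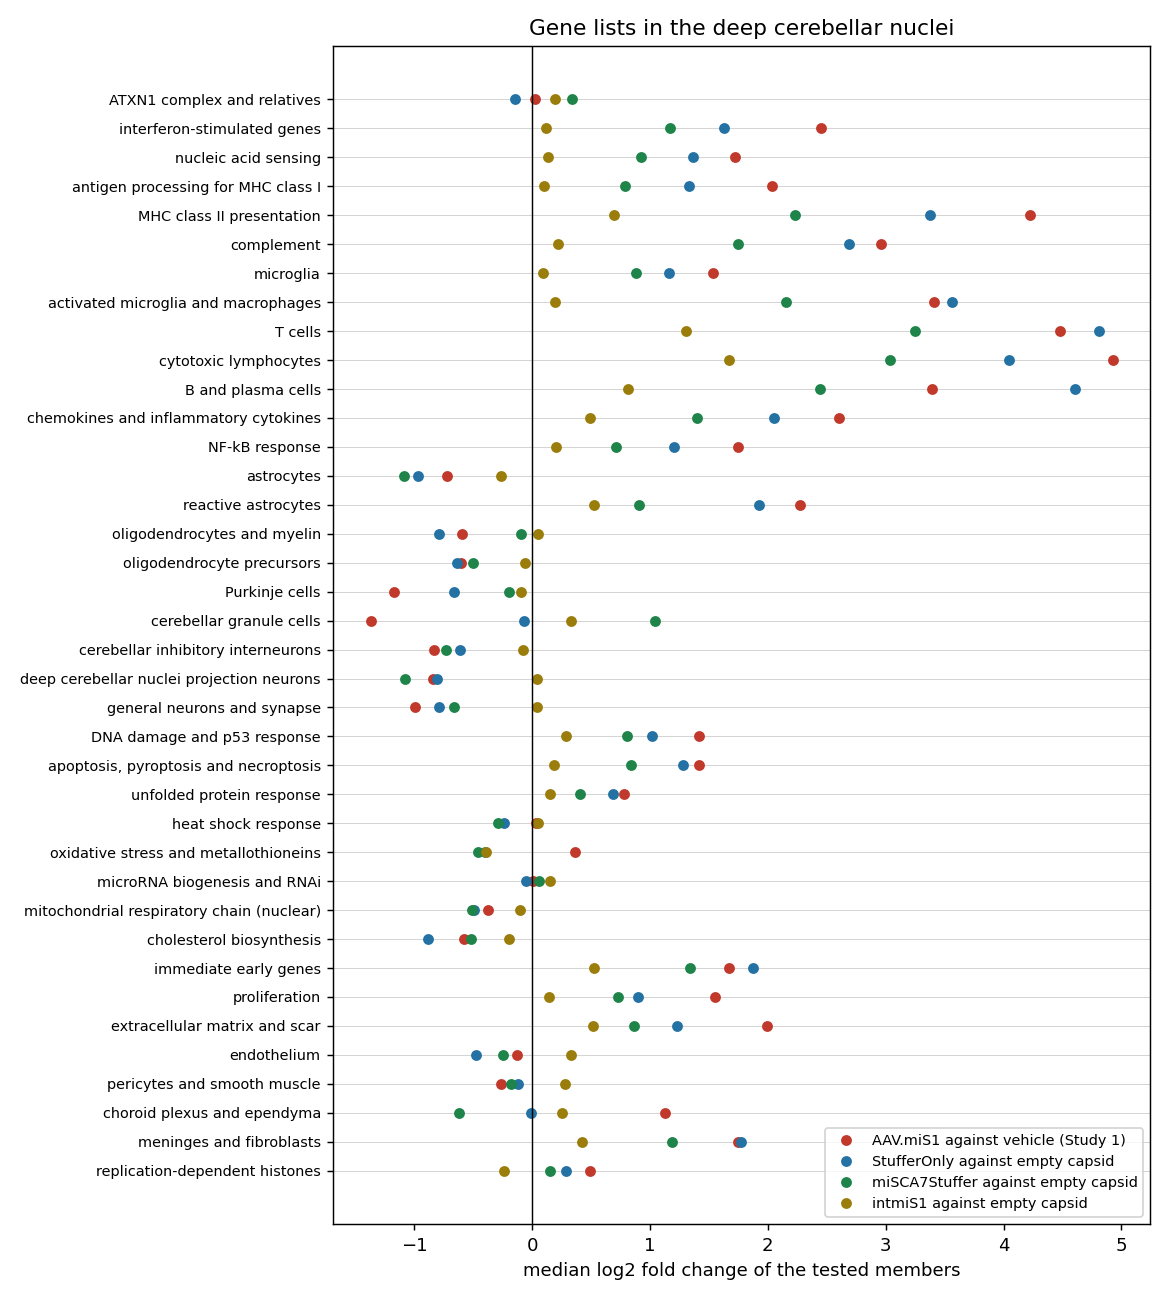
Median log2 fold change of the tested members of each list in AAV.miS1 against vehicle and in StufferOnly, miSCA7Stuffer and intmiS1 against empty capsid. MHC class II genes stand at 4.23, 3.38, 2.23 and 0.70 in that order.

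By edgeR, 3219 of 20882 genes passed for StufferOnly, 2424 up and 795 down (6782 at an unadjusted p under 0.05, 5133 by DESeq2). Of these, 3218 did not overlap between groups, and of all genes 5588 were higher and 4664 lower without overlap, where chance gives 1044 each way, or 10% both ways. The count rested on single libraries: 0, 1 and 20 without empty capsid replicates 1 to 3 (5345 at an unadjusted p under 0.05 for the 0), 2593, 21 and 53 without StufferOnly replicates 1 to 3, and 7255 without miSCA7Stuffer replicate 1, which enters the fitted spread. It was 3164 and 2753 without miSCA7Stuffer replicates 2 and 3.

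**Figure D3:**
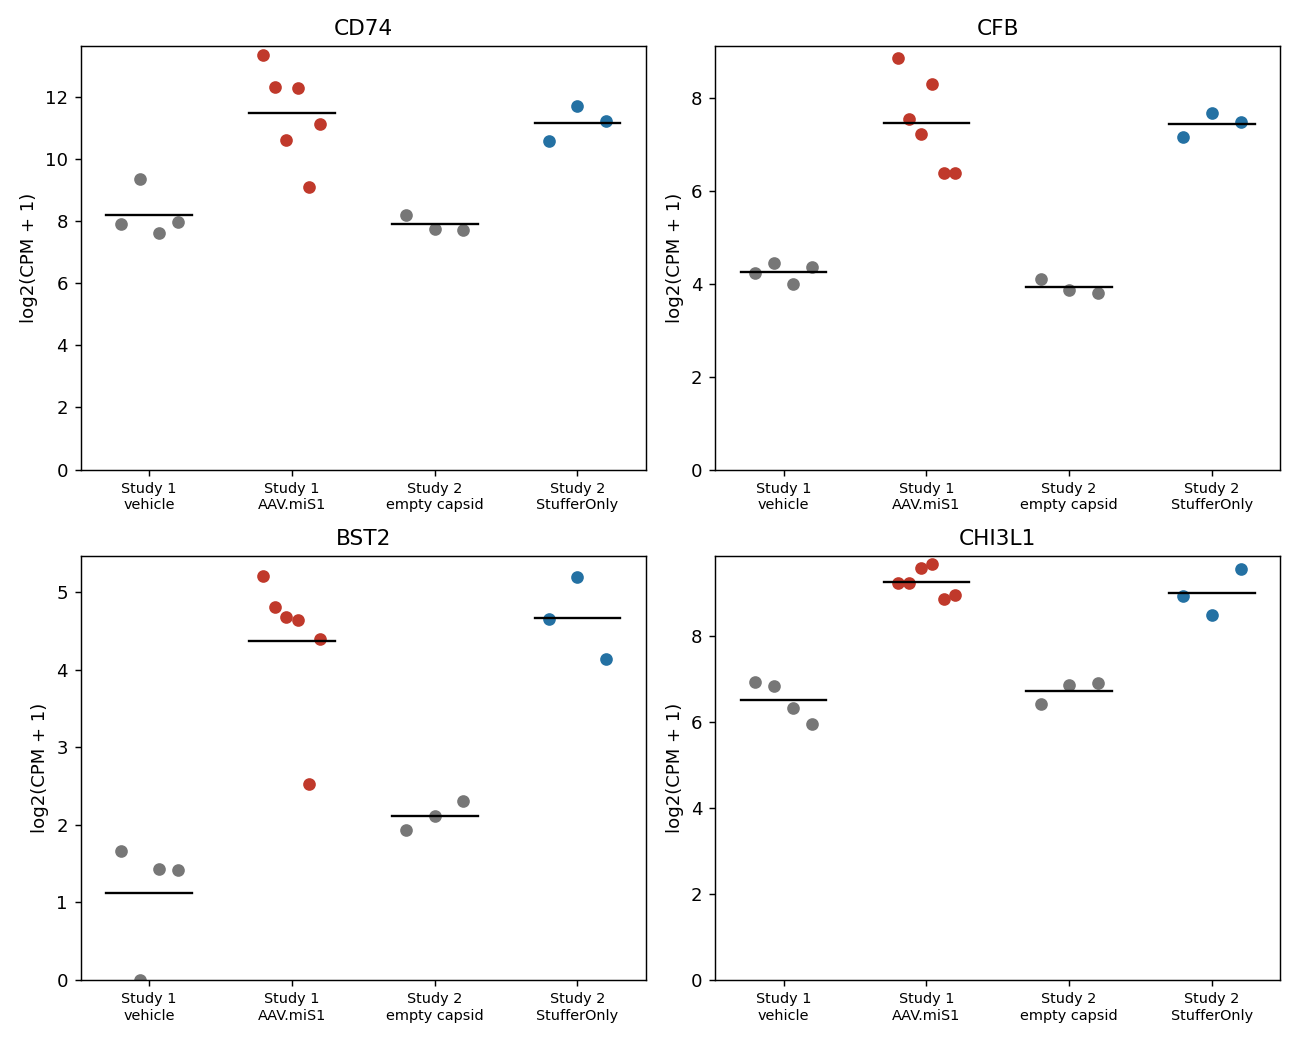
CD74, CFB, BST2 and CHI3L1 as log2(CPM + 1) in each library of Study 1 vehicle and AAV.miS1 and of Study 2 empty capsid and StufferOnly, with a line for the mean. CHI3L1 stands at a mean of 94.1 and 624.5 CPM in Study 1 and 106.4 and 534.6 CPM in Study 2.

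In animals given miSCA7Stuffer, which by its label adds the ATXN7 microRNA to the filler, 2 libraries carried high macrophage genes and replicate 1 did not. GPNMB was 2249 ± 1985 CPM (SD, n = 3, 6.89 to 3785) against 5.38 ± 2.18 (n = 3, adjusted p = 0.134), and CD68 372.0 ± 311.7 (17.8 to 604.6). AQP4, the water channel of astrocytes, was 952.7 ± 413.7 against 2544 ± 121.2 CPM, lower in 3 of 3 libraries without passing (adjusted p = 0.135). The 1 gene that passed was TMEM266, a voltage-sensing membrane protein of granule cells, at 23.1 ± 4.93 against 3.87 ± 0.619 CPM (2.58, SE 0.21, adjusted p = 0.0229, higher in 3 of 3, with adjusted p from 7.86e-22 to 0.311 over the alternatives). Neither ATXN7 (31.0 ± 5.93 against 34.5 ± 1.89 CPM, -0.16, adjusted p = 0.553) nor ATXN1 (40.9 ± 17.0 against 52.1 ± 6.18, -0.35, 0.443) passed. Without replicate 1 ATXN1 was at -0.73 with an adjusted p of 0.0219, in a range of 0.0219 to 0.86 over the alternatives. DCN projection neurons had a median of -3.04 without that replicate, so a change in the cells sampled is not set apart there.

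The lists for miSCA7Stuffer moved by camera although no member passed singly by edgeR. T cells had a median of 3.25 (0 of 24 past the threshold, 14 adjusted over the list alone, camera adjusted p = 2.79e-06), cytotoxic lymphocytes 3.04 (0 of 13; 10), MHC class II 2.23 (0 of 9; 9), activated microglia and macrophages 2.15 (0 of 21; 14 with 1 down), complement 1.75 (0 of 16; 13) and interferon-stimulated genes 1.17 (0 of 39; 19 with 1 down). The medians of T cells and cytotoxic lymphocytes were the same with absent members at their bound. Downward went astrocytes (-1.08; 2 adjusted over the list alone), DCN projection neurons (-1.08; 0), inhibitory interneurons (-0.73; 0) and the respiratory chain (-0.51; 7). Granule cells were at 1.04 (0.0553, and -0.02 without replicate 1), Purkinje cells at a median of -0.19 and a mean of 0.03 with the test pointing down (0.0553, and a median of -1.0 without replicate 1), and oligodendrocytes at -0.10 (0.27). In all, 26 lists passed with the preset correlation and 0 with an estimated correlation (lowest adjusted p 0.486).

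For miSCA7Stuffer edgeR called 1 of 20882 genes (4808 at an unadjusted p under 0.05, 2159 by DESeq2). Without miSCA7Stuffer replicate 1, the library with 1.64 vector RPM, it called 6983 genes, 3367 up and 3616 down, and TMEM266 was among them. It called 0 without any single one of the other 8 libraries, that is, without miSCA7Stuffer replicates 2 or 3, empty capsid replicates 1, 2 or 3, or StufferOnly replicates 1, 2 or 3 (2780 to 4740 at an unadjusted p under 0.05). In the lists, recomputed without replicate 1 after the data were seen, 33 of 39 interferon-stimulated genes rose (median 1.60), 17 of 24 T cell genes (3.65) and 17 of 21 macrophage genes with 1 down (2.58). DCN projection neurons had 13 of 19 down (-3.04, camera adjusted p = 4.68e-07, and 0.206 with an estimated correlation), general neuronal genes 20 of 29 down (-1.79), Purkinje cells 13 of 24 down (-1.0) and granule cells 1 up and 5 down of 18 (-0.02). Inhibitory interneurons had 1 up and 11 down of 15 (-1.66), astrocytes 12 of 15 down (-1.57) and the respiratory chain 24 of 28 down (-0.84).

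Set against StufferOnly, miSCA7Stuffer libraries had higher myelin genes as a list, with no gene past the threshold, while lower immune lists and higher granule cell genes rested largely on replicate 1, the library with 1.64 vector RPM. StufferOnly libraries also held RNAi cassette reads, so this comparison does not isolate the ATXN7 microRNA. ATXN7 was 31.0 ± 5.93 CPM (SD, n = 3) against 43.3 ± 3.2 (n = 3), lower in 3 of 3 libraries (-0.48, SE 0.16, adjusted p = 0.364, range 0.0732 to 0.743 over the alternatives). It passed when adjusted over the 2 vector target genes alone, which corrects for little. The myelin gene MAL was 71.8 ± 8 against 31.2 ± 0.844 CPM (1.20, adjusted p = 0.223, higher in 3 of 3), and PAQR6, a membrane progesterone receptor, 519 ± 38.4 against 191.4 ± 32.8 (1.44, 0.132, higher in 3 of 3). Oligodendrocytes and myelin stood at 0.68 (0 of 16 by edgeR, 13 adjusted over the list alone, camera adjusted p = 1.9e-12, and 0.508 with an estimated correlation) and granule cells at 1.27 (0 of 18; 0, 0.000247, and 0.541). T cells stood at -1.25 (2.4e-05), MHC class II at -1.14 (0.000211), macrophages at -1.11 (1.16e-05), complement at -0.88 (6.54e-05) and interferon-stimulated genes at -0.44 (0.000276). None of these passed with an estimated correlation (0.508 to 0.628). By edgeR 0 of 20882 genes passed (2117 at an unadjusted p under 0.05, 413 by DESeq2), 343 did without miSCA7Stuffer replicate 1 and 1 without empty capsid replicate 3.

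The lists of miSCA7Stuffer against StufferOnly were recomputed without miSCA7Stuffer replicate 1 after the data were seen. Interferon-stimulated genes then stood at -0.00 (camera adjusted p = 0.94) and T cells at -0.75 (0.0617), and neither passed. MHC class II stood at -0.58 (0.0173), macrophages at -0.52 with 1 of 21 down (0.00351) and complement at -0.32 (0.0435). Granule cells stood at -0.04 with 1 of 18 down (0.94). Oligodendrocytes and myelin stayed higher at 0.75 with 2 of 16 up (2.88e-08), and DCN projection neurons stood at -2.10 with 8 of 19 down (9.27e-07) and general neuronal genes at -0.84 with 5 of 29 down (8.78e-06). With an estimated correlation the adjusted p of these lists ranged from 0.677 to 0.984.

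In animals given intmiS1, the immune genes that rose with AAV.miS1 and StufferOnly did not pass against empty capsid. Interferon-stimulated genes had a median of 0.12 (0 of 39 by edgeR, 0 up and 1 down adjusted over the list alone, camera adjusted p = 0.676), macrophages 0.20 (0 of 21; 0, 0.747), complement 0.22 (0 of 16; 0, 0.526), MHC class II 0.70 (0 of 9; 0, 0.089) and T cells 1.31, or 1.24 with members absent from empty capsid at their bound (0 of 24; 0, 0.0786). Purkinje cells (-0.09, 0.42), DCN projection neurons (0.04, 0.553), general neuronal genes (0.04 with a mean of -0.01, 0.813) and oligodendrocytes (0.05, 0.611) did not pass either. CDKN1A was 101.9 ± 34.2 CPM (SD, n = 3, 76.6 to 140.8) against 1.25 ± 0.437 (n = 3), higher in 3 of 3 libraries, and did not pass (6.33, adjusted p = 0.576). ATXN1 was 41.1 ± 11.3 against 52.3 ± 6.2 CPM (-0.35, adjusted p = 0.722), and ATXN7 42.5 ± 9.52 against 34.7 ± 1.91 (0.29, 0.661). These lists passed by camera with the preset correlation: cytotoxic lymphocytes (1.67, or 1.64 with absent members at their bound, 0.00352), immediate early genes (0.53, 0.000304), extracellular matrix (0.52, 0.00761), p53 response (0.28, 0.0138), reactive astrocytes (0.53, 0.0184), chemokines (0.49, 0.021) and endothelium (0.33, 0.045). None did with an estimated correlation (0.492 to 0.95).

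For intmiS1 edgeR called 0 of 21501 genes (1831 at an unadjusted p under 0.05, 46 by DESeq2). It called 1852 without intmiS1 replicate 3, which leaves only the 2 libraries counted by another program, so that group and file type cannot be told apart there. With only featureCounts libraries, which leaves 1 intmiS1 library assumed to vary like the other groups, it called 0 (324 at an unadjusted p under 0.05). It called 1 without miSCA7Stuffer replicate 1. RPS13, a ribosomal protein, was among the smallest p (42.6 ± 34.6 against 2.27 ± 0.581 CPM, 4.21, adjusted p = 0.576) and followed the file type, with 2.58 CPM in the featureCounts library.

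Whether AAV.miS1 and intmiS1 differed in their effects was tested as a difference of the changes, each against its own control. The change in interferon-stimulated genes was larger with AAV.miS1 by a median of 2.29 log2 (0 of 39 by edgeR, 31 adjusted over the list alone, camera adjusted p = 1.66e-10, and 0.333 with an estimated correlation), with all 39 above 0. MHC class II differed by a median of 3.625 (0 of 9; 9, 0.000646), complement by 2.51 (0 of 16; 16, 1.87e-06), macrophages by 3.08 (0 of 21; 16, 8.91e-07) and proliferation by 1.62 (0 of 21; 10, 1.1e-06). In the other direction went granule cells (-1.65, 3.98e-07), Purkinje cells (-1.15, 7.04e-05), general neuronal genes (-1.03, 3.98e-07), DCN projection neurons (-0.86, 0.000834) and oligodendrocytes (-0.75, 5.79e-07). None of these passed with an estimated correlation (0.333 to 0.387). The p53 response did not pass (0.74, 0.0807), and neither did ATXN1 (-0.34, adjusted p = 0.634) or ATXN7 (-0.15, 0.82). By edgeR 0 of 16537 genes passed (2865 at an unadjusted p under 0.05, 401 by DESeq2). Without intmiS1 replicate 3 it was 872, without AAV.miS1 replicate 5 it was 328, without miSCA7Stuffer replicate 1 it was 7, and without vehicle replicate 1 it was 1. Study, capsid control and depth differ together with the construct in this comparison.

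In Study 1 small RNA, the artificial microRNA miS1 was read in every AAV.miS1 library and varied more than 100-fold in count. It had 4502, 68887 and 526 counts with AAV.miS1 and 8, 0 and 10 with vehicle (2675 ± 3750 against 0.756 ± 0.657 RPM, SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest the design allows). Per 1000 microRNA counts these were 4.11, 23.2 and 0.457 in the AAV.miS1 libraries, where 16, 8 and 49 endogenous microRNA genes had more counts than miS1. Small RNA reads assigned to the ATXN1 gene were 41.5 ± 39.2 against 3.44 ± 1.67 RPM (two-sided exact permutation p = 0.1, the smallest the design allows). They had 139, 843 and 49 counts with AAV.miS1, highest and lowest in the same libraries as miS1, and 20, 24 and 45 with vehicle. Because miS1 is aimed at ATXN1, reads of miS1 assigned to that gene are not set apart from its own, and this was not tested. AAV.miS1 replicate 2 stood apart in immune and red cell microRNAs: miR-155 was at 77.6 RPM there and 0.42 to 4.76 in the other libraries, miR-21 at 3640 against 443 to 938, and miR-451 of red blood cells at 178 against 1.62 to 10.3. MicroRNA genes held 23.0%, 30.1% and 23.3% of counts with AAV.miS1 and 30.9%, 26% and 29.3% with vehicle.

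No endogenous microRNA passed in Study 1 small RNA: edgeR called 0 of 8311 genes, 212 of them microRNA genes (52 at an unadjusted p under 0.05, 0 by DESeq2), and 642 without AAV.miS1 replicate 2. Fitted log2 changes were 4.11 for mir-155, 4.02 for mir-451, 2.72 for MIR142, 2.004 for mir-21 and 0.11 for mir-124a-2, all with an adjusted p of 1, and those of mir-155 and mir-21 turned to -2.21 and -2.05 without that library. These changes depend on scaling: in the fit of all 6, TMM factors were 2.48, 0.375 and 1.91 with AAV.miS1 and 0.683, 0.773 and 1.07 with vehicle. Without TMM, miR-21 was 443 and 466 RPM in AAV.miS1 replicates 1 and 3 and 938, 540 and 480 with vehicle. Brain-enriched microRNAs had a median of 0.07 with the test pointing down (0 of 18; 0 adjusted over the list alone, camera adjusted p = 0.00113, and 0.601 with an estimated correlation). The let-7 family stood at -0.10 (0 of 8; 0, 0.00745, and 0.601) and immune-associated microRNAs at 0.67 with the test pointing down (0 of 14; 0, 0.122, and 0.675). Red cell microRNAs had 4 members tested.

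In Study 2 small RNA, 5 of 6 libraries held 24899760 to 45850915 reads, of which 99.946% to 99.989% were unmapped (empty capsid replicate 2: 8838518 reads, 31.739%). The few mapped reads limit what these libraries show, and whether these are the intended tables is open. In the 5 libraries microRNA genes had 0 counts, which allows shares of up to 0.185%, 0.107% and 0.134% with intmiS1 and 0.665% and 0.865% with empty capsid. These 5 libraries held 7457 counts together, of which SNORD115 genes took 2763 and SNORD116 genes 2337, both small nucleolar RNAs of neurons, and 82.3% of counts fell in genes with small nucleolar RNA names. Empty capsid replicate 2 held 321 microRNA counts in the sense column, or 0.116% of its sense total, in 29 genes. Its reverse column, not used here, held 1648126 counts. By edgeR 0 of 22 genes passed (0 at an unadjusted p under 0.05), and DESeq2 could not be fitted. It was 5 without empty capsid replicate 2 and 3 without empty capsid replicate 3.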

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

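Of the tests in this part, those of miSCA7Stuffer replicate 1 and of the share of unmapped reads were chosen only after the result was seen. Groups of 4 to 10 libraries were searched for a lowest or highest library far from the others, and 14 of 210 such tests picked one out, where chance alone gives 10.5.

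Vehicle replicate 2 of Study 1 stood apart by its total of 87700 counts, the next lowest being 2270423. With so few counts it also had the lowest BST2 (0 CPM, next 1.66), CNTN4 (0 CPM, next 22.2) and TUT7 (10.4 CPM, next 57.7). At that depth a count of 0 allows up to 3 counts. Vehicle replicate 3 had the highest NKG7 (0.281 CPM), THEMIS (0.281), GZMK (0.562) and MMP9 (0.281), each against 0 in the others, and the lowest EDEM1 (51.5, next 60.6). Vehicle replicate 4 had the highest CR1 (0.663, next 0) and the lowest TNRC6C (118, next 161). With 3439609 counts in replicate 3 and 2976749 in replicate 4, values under 1 CPM are a few reads at most. The NKG7, THEMIS, GZMK, MMP9 and CR1 values therefore do not set these libraries apart. Vehicle replicate 1 had the highest APAF1 (29.4, next 21.5). Among AAV.miS1 libraries, replicate 5 had the lowest BST2 (4.77 CPM, next 20) and replicate 1 the highest ATXN1 (90.2 CPM, next 61.9).

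Reads of the AAV genes Rep2 and Cap1, which were part of no comparison, appeared in the vector groups of Study 2, pooled over each group, above the upper limit in empty capsid libraries. Rep2 stood at 13.9 RPM with StufferOnly, 10.6 with miSCA7Stuffer and 24.7 with intmiS1 (limit 0.103). Cap1 stood at 10.1, 9.53 and 19.9 (limit 0.0724). Single libraries and the file type moved these values. intmiS1 replicates 1 and 2 came as STAR counts and replicate 3 as featureCounts, so the pooled intmiS1 values cannot be set against the other groups. Replicate 3, counted as the other groups were, lay below every StufferOnly library for both genes. Rep2 was 11.3, 26.6 and 7.79 RPM in StufferOnly replicates 1 to 3, 0, 18.8 and 17.1 in miSCA7Stuffer and 101, 87.5 and 3.1 in intmiS1. Cap1 was 8.61, 16.7 and 6.92, then 0.0606, 17.8 and 14, then 79.1, 67.1 and 3.31. miSCA7Stuffer replicate 1 was above neither limit. No explanation was tested.

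Macrophage genes were higher in vehicle replicate 2 than in any other vehicle library. Reads mixed in from an AAV.miS1 library would leave few of 119 response genes outside their counting intervals, and 4.2% to 8.4% lay outside with AAV.miS1 replicates 1 to 4 and 6 as the source, at fitted shares of 5.23% to 32.1%. Replicate 5 would need an impossible share of 161% (13.4% outside), so the fit fails for it. A local macrophage response would raise the macrophage list without interferon-stimulated genes. Against the highest other vehicle library the first stood at 0.95 and the second at -1.28 (log2). The mixing test rests on 201 counts, and even at the impossible share of 161% only 13.4% lay outside, so it could exclude little. The test of the lists is limited by depth as well. At 87741 counts in this library, weakly expressed genes can read 0, as BST2 did. Depth alone can thus lower the interferon-stimulated list, and the -1.28 does not show that these genes stayed low. Each test went the way of its own explanation, so they do not decide between the explanations.

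Empty capsid replicate 2 of Study 2 small RNA held 277509 counts in the sense column where the other 5 held 347 to 2795. It held 1648126 in the reverse column, so its sense counts are those of its minor strand. Sense counts were 14.4% of its stranded counts, against 72.4% to 82.2% in the other 5. A small RNA library like the others at greater depth is argued against, since 44 genes held 96.1% of the counts of the other 5 and 0.00216% of its own. Its profile is consistent with total RNA in place of small RNA, with a mean Spearman correlation across genes of 0.857 with the DCN empty capsid libraries and 0.693 with Study 1 small RNA vehicle libraries (genes are not independent replicates). No biological explanation was tested.

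miSCA7Stuffer replicate 1 did not share the response of the other miSCA7Stuffer libraries. Over the 2424 genes that rose with StufferOnly, its median log2 difference from empty capsid was 0.12, against 1.26 and 1.22. A swap of labels with an empty capsid library is argued against, because no empty capsid library held more than 0.281 vector RPM. Little vector in the tissue sampled may account for it, with 1.64 vector RPM, above the pooled empty capsid limit of 0.31 and 0.636% of the lower of the others. Without replicate 1, the median of granule cell genes in the group went from 1.04 to -0.02 against empty capsid. That of DCN projection neurons went from -1.08 to -3.04, so replicate 1 also stood apart in cell-type genes. Whether the dose missed the nuclei or the sample was taken beside it stays open.

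AAV.miS1 libraries with over 15% unmapped reads (replicates 5 and 6) showed a smaller response. Over 1926 genes that rose with StufferOnly and were tested in Study 1, the median log2 difference from vehicle (replicate 2 left out throughout for its few counts) was 0.52 within that set and 1.59 within the set under 15%. A difference in library making between the sets cannot be told apart from a weaker response in these animals: the vehicle libraries of the sets differed by 0.09, but the set under 15% has 1 vehicle library. A weaker response in the animals of the 2 libraries is consistent with the 0.52, which is above 0 and smaller than in the other set. The libraries of the 6 animals stood at 2.11, 1.46, 1.27, 1.75, 0.31 and 0.70.

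Other splits of the libraries into groups of the same sizes were counted. In Study 1, 4 of 100 splits drawn from 210 gave as many genes as the real 1004, the real one included. That share is under 0.05 in this draw, but another draw might give 0.05 or more, so chance is not firmly excluded. The highest other split called 5236 genes, several times the real count, which points to a structure of the samples. It set AAV.miS1 replicates 1 to 4, the libraries with the larger response, against AAV.miS1 replicates 5 and 6 and all 4 vehicle libraries. It parts the libraries as the unmapped share does, except for vehicle replicate 1 (9.558% unmapped), so the unmapped share and the size of the response are not separated by it. Others called 2881 and 2326. Within the set over 15% unmapped 123 genes passed, and 148 with the set as a covariate. In Study 2 and in small RNA, 10 splits are too few for a share under 0.05. StufferOnly gave 3219 genes and the highest other split 0 (1 of 10 as large), miSCA7Stuffer against empty capsid 1 and 0 (1 of 10). miSCA7Stuffer against StufferOnly gave 0 and 0 (10 of 10), intmiS1 0 and 0 (10 of 10), Study 1 small RNA 0 and 2 (10 of 10) and Study 2 small RNA 0 and 0 (10 of 10).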

How the results depend on the processing

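Tests with the unmapped share as a covariate, within the sets over and under 15% unmapped, with a robust spread, with total counts alone in small RNA, and of the lists without miSCA7Stuffer replicate 1, with the replicate block or with the unmapped covariate were chosen after seeing the data. The cause was not tested for any change given here, except where fewer libraries or genes are named.

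Study 1 DCN gave 1036 genes with RLE, 982 without a filter, 857 with the unstranded column, 713 with the identifier format as a covariate and 920 with a robust spread, each within 1.5 times 1004. DESeq2 gave 1816. Leaving out single libraries gave 0 to 2300. The unmapped covariate gave 148, the set over 15% 123 and the set under 15% 0, both sets with fewer libraries. SOX10 turned to 0.00 in the set over 15%. The lists passed 0 with an estimated correlation, 28 to 30 without single libraries and 29 with the unmapped covariate.

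StufferOnly against empty capsid gave 3189 genes with RLE, 2776 without a filter, 3299 with a replicate block (equally numbered libraries correlated at -0.07 to 0.06) and 3189 with a robust spread. DESeq2 gave 5133, only the 6 libraries compared 6314, and leaving out single libraries 0 to 7255. The share of rises was 75.3%, 64.7% with DESeq2 and 48.5% without miSCA7Stuffer replicate 1. The lists passed 0 with an estimated correlation and 29 with the block.

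miSCA7Stuffer against empty capsid gave 2159 genes with DESeq2, 0 with only the 6 libraries compared, 1 with the block (-0.09 to 0.04), and 0 to 6983 without single libraries. The lists passed 0 with an estimated correlation and 28 without replicate 1 or with the block. Against StufferOnly it gave 1 without a filter, 413 with DESeq2, 0 with the block, and 0 to 343 without single libraries. There the lists passed 24, 0 with an estimated correlation, 15 without replicate 1 and 26 with the block.

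intmiS1 against empty capsid gave 46 with DESeq2, 1 with only the 6 libraries compared, 0 with only featureCounts libraries, the other STAR column or the block (-0.10 to -0.03), and 0 to 1852 without single libraries. The difference of effects gave 1 with RLE, 401 with DESeq2 and 0 to 872 without single libraries.

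Study 1 small RNA gave 21 without a filter, 0 with microRNA genes alone, total counts alone or the block (-0.09 to 0.18), and 0 to 642 without single libraries. Study 2 small RNA gave 23 without a filter, 0 with the block (-0.32 to -0.05), and 0 to 5 without single libraries. RLE, DESeq2 and microRNA genes alone could not be fitted there and were not run.

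Single genes that changed sign were few, and most had not passed. Without single libraries AHSP ranged from -0.95 to 0.58 with StufferOnly and from -0.99 to 0.37 with miSCA7Stuffer (both highest without empty capsid replicate 3), and from -0.47 to 0.41 between these groups (0.41 without StufferOnly replicate 2). HBA ranged there from -0.48 without miSCA7Stuffer replicate 1 to 0.49, and was -0.20 without StufferOnly replicate 3. With intmiS1, ATXN7 turned to -0.13 and TBR1 to -0.75 with only featureCounts libraries. In the difference of effects, SDHC turned to 0.22 and ATXN7 to 0.35 without the 2 intmiS1 libraries of the other file type.

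In Study 1 small RNA, without single libraries, mml-mir-155 ranged from -2.21 to 4.66, mml-mir-451 from -2.78 to 4.57, MIR142 from -1.95 to 3.43, mml-mir-221 from -1.79 to 2.91, mml-mir-21 from -2.05 to 2.52 and mml-mir-124a-2 from -1.74 to 0.52, each lowest without AAV.miS1 replicate 2. With the block they stood at -0.65, -0.81, -0.28, -0.27, -0.35 and -0.67. TMM factors in the main fit ranged from 0.375 to 2.48, so these values depend on the scaling. mml-mir-124a-2 turned to -0.15 without a filter, -0.14 without vehicle replicate 3 and -0.07 with total counts alone. ATXN7 there turned to 0.03 with RLE, 0.01 with DESeq2, 0.00 and 0.09 without AAV.miS1 replicates 2 and 3 (range -0.26 to 0.09), and 0.96 with total counts alone.

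Depth limits vehicle replicate 2 of Study 1, at 87741 counts, while 5 libraries of Study 2 small RNA are limited by unmapped reads (99.946% to 99.989%), which left 347 to 2795 counts.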

Other observations

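The test of vector reads against the response was chosen only after the result was seen. The test of shared genes was set before it.

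AAV.miS1 and StufferOnly are labelled with different cargo, but stuffer sequence was read in both. In Study 1 small RNA it had 5, 78 and 0 counts with AAV.miS1 and 0 in each vehicle library. StufferOnly DCN libraries held 290, 490 and 193 stuffer RPM. AAV.miS1 and StufferOnly were compared with different controls in different animals. A shared set of genes could therefore reflect a response to vector, shared sequence included, or to tissue injury in common. Among 13377 genes tested in both, 773 rose in both, 5.56 times the 139 that independent lists would share, and 13 fell in both against 2.04. None moved in opposite directions past the threshold. Across genes the log2 changes correlated (Pearson 0.89, Spearman 0.84), though genes are not independent replicates. The hypothesis needs animals given other cargo in the same study, and empty capsid controls in Study 1, to be tested further.

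A response that grows with the vector left in the tissue was tested as 1 relation across the 6 AAV.miS1 libraries, between log2 vector RPM and the mean of the macrophage genes. Spearman's rho was -0.09 (exact permutation p = 0.919) and Pearson's r 0.19 (exact permutation p = 0.7, two-sided). Without the 2 libraries farthest from the median of the vector reads r was 0.91, so the relation rests on which libraries are kept, and 6 libraries cannot settle it.

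FDFT1 rose with StufferOnly while 7 other genes of cholesterol synthesis fell. The tables count reads on either strand and in every gene they overlap, so reads of a neighbouring gene are not set apart from its own, and no test was made. The vector feature for miS1 had 38 and 28 counts in miSCA7Stuffer replicates 2 and 3, a group whose label names no ATXN1 construct, and 0 in StufferOnly libraries. The STAR tables of Study 1 DCN hold 0 there in every library, and likewise for the cassette, primary microRNA and stuffer features, so those zeros do not show absence. Rep2 reads in intmiS1 replicate 1 were 502 in the reverse column and 20 in the sense column, and 405 and 20 in replicate 2.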
